A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

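Micro-C XL contact maps of budding yeast were analysed from 4 libraries, 1 each of growing cells (Log), quiescent cells (Q), and quiescent SMC4 tet-off cells with doxycycline (SMC4-off) and without it (SMC4-on). Per the labels' protocols, Log cells came from 200 mL cultures at an optical density of 0.55 and quiescent cells from 25 mL cultures of 7 days by Percoll gradient. Cells were fixed with 3% formaldehyde for 10 min, permeabilised with zymolyase (250 ug/mL for 30 min in Log, 1 mg/mL for 1.5 h in quiescent cells), crosslinked with 3 mM disuccinimidyl glutarate for 40 min, and digested with micrococcal nuclease for 20 min at an amount titrated per experiment. The permeabilisation therefore differed between Log and the quiescent libraries. Both Log and Q name strains 5781 and 5783, and both SMC4 libraries strains 6909 and 6910, so each library may pool a pair of strains. The deposited maps of Log, Q and SMC4-off are named as merged and that of SMC4-on is not, so SMC4-on may rest on fewer preparations than the others. How strains were combined is not given in the sources used here.

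The reads were aligned with Bowtie2 to sacCer3 (R64), per the submitters' processing notes. Read-pair filters, duplicate removal and the scope of balancing are not given in the sources used here. The authors deposited matrices of pairs of bins, at 5 kb over the whole genome and at 1 kb and 200 bp for each chromosome. In each, the deposited count column holds whole numbers of read pairs, and the deposited signal column holds the same contacts after iterative correction (ICE), which scales bins so that their sums become equal. Balancing removes differences in coverage between bins, so a region with fewer reads is raised to the level of others, and bins with few reads have no balanced value. All 16 chromosomes had the length of the reference, from which genes and other features were taken: 6002 protein-coding genes, 275 tRNA genes, 16 centromeres, 434 Ty or LTR features and 352 origins of replication. No columns of other samples were used (0).

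Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. Only bins balanced in all 4 libraries were used: 94.3% of 60365 bins of 200 bp, 94.1% of 12079 bins of 1 kb and 93.6% of 2423 bins of 5 kb. Contact shares by distance came from 1 kb bins, the share at 200 to 800 bp from 200 bp bins, and the share between chromosomes from 5 kb bins. The insulation score of a bin edge was the log2 of the mean balanced contact in a square across it over the chromosome mean, with at least 0.5 of the square usable. Squares were 10 kb at 1 kb bins (large boundaries) and 2 kb at 200 bp bins (fine boundaries). Boundaries were minima with a prominence of at least 0.2 (large, 5 kb apart) or 0.5 (fine, 800 bp apart). Boundaries were matched between libraries within 2 kb (large) or 0.4 kb (fine). They were compared with features within 1 kb (large) or 200 bp (fine), against 10000 circular shifts along the chromosomes.

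Contact between centromeres (the centromere bin and 1 bin on each side), between telomeres (outermost 30 kb) and between tRNA genes on different chromosomes (without bins within 30 kb of a centromere or end) was divided by the mean contact between chromosomes. Contact between the 100 kb on each side of the rDNA, and between windows of 5 kb around HML and HMR, was divided by that at the same reference distances on other chromosomes. Within-gene contact was the sum over pairs of 200 bp bins inside a gene, at least 2 bins apart, over the chromosome's mean at the same distances, for genes of at least 1000 bp with a mean of at least 50 contacts. Log2 ratios of genes are relative to the median of all genes. A gene counts as uncertain by the percent of its 50-base windows that recur in the genome. Read coverage was taken from counts in 5 kb bins before balancing, relative to bins within 400 kb of centromeres, chromosome XII left out.

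With 1 library per group no test between conditions was possible, so no p-value, standard error or number of changed genes is given. Counts of contacts carry 95% counting intervals, and shares carry exact Clopper-Pearson intervals. Read pairs may include duplicates, so the intervals cover counting error only. Gene lists were chosen from known pathways before the data were examined, as were the comparisons, the rule for named genes and the first set of alternatives. The median of each list was placed among 10000 random lists of the same size matched on contact, which describes these libraries. The genes named are the 10 highest and 10 lowest of Q over Log and of SMC4-off over SMC4-on, SMC4, the 5 boundaries with the largest difference each way, and up to 4 members of each list outside the central 95%. Random draws used seed 1.

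The boundary and gene steps were tested on simulated data. On maps with planted boundaries, between 98.3% (SMC4-off) and 99.3% (Log) of planted large boundaries were found. All were planted at the same strength, and none near the prominence threshold. These shares therefore do not give the sensitivity to weaker boundaries. Maps simulated without boundaries gave 73 (Log) to 76 (SMC4-on) large calls and 67 (Q) to 85 (SMC4-off) fine calls, of which 28 to 29 and 40 to 57 lay beside bins without a balanced value. Near tRNA genes lay 7, 10, 6 and 7 of these large calls (Log, Q, SMC4-off, SMC4-on), where shifts gave 2.91, 2.97, 2.96 and 3.00, and 4, 6, 6 and 6 of the fine calls, where shifts gave 0.706, 0.642, 0.843 and 0.743. Of 200 genes given a log2 change of 0.58, 99% (Q over Log), 98% (SMC4-off over SMC4-on) and 98.5% (SMC4-on over Q) were among the 200 largest. Only counting noise was simulated: unchanged genes had an SD of 0.078 in Q over Log, where the measured genes had 0.21. Of 200 random gene lists 8 (4%) lay outside the central 95%, as did 8 of 200 random boundary sets.

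Alternatives covered bin size, balancing, square size, prominence, depth, near distance, gene length, expected contact, and the spans of landmarks. Further alternatives, among them the regions with lower coverage left out, background subtraction, shares of all contact, genes relative to their neighbours within 50 kb and squares free of bins without a balanced value, were added after the data were seen. No library was left out in turn, as each group is 1 library.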

Results

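Chromosome folding was measured in budding yeast (Saccharomyces cerevisiae, W303 background) by Micro-C XL, a chromosome conformation method in which crosslinked chromatin is digested to nucleosomes with micrococcal nuclease and neighbouring fragments are ligated, so that each sequenced read pair records a contact between a pair of nucleosomes. There were 4 groups with 1 library each: growing wild-type cells (Log), purified quiescent wild-type cells (Q), and quiescent cells whose SMC4 gene carried a tet-off construct, grown with doxycycline (SMC4-off) or without it (SMC4-on). SMC4 encodes a core subunit of condensin, a ring-shaped complex that folds chromosomes. The libraries held 63792408 contacts in Log, 45310337 in Q, 69408765 in SMC4-off and 32545161 in SMC4-on, of which 42864265, 25285384, 33604655 and 18205651 lay within chromosomes. No group had a replicate, so differences between libraries carry no test. Intervals given with values are 95% counting intervals and cover counting error only, and standard deviations (SD) over the 16 chromosomes describe the spread within a pair of libraries.

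The comparison of Q with Log asks how chromosomes are folded in quiescent cells. In Q, contact was higher between distant loci and between chromosomes, and lower over the span of several genes. Of balanced contact within chromosomes at 1 kb or more, 21.7% spanned 10 to 60 kb in Q and 25.8% in Log (log2 ratio -0.25, lower on all 16 chromosomes, SD over chromosomes 0.031). At 60 to 200 kb the share was higher in Q (log2 ratio 0.32), and over 200 kb it was 7.75% in Q against 5.25% in Log (log2 ratio 0.56, higher on 16 of 16 chromosomes). Contact between chromosomes made up 43.9% of the total in Q and 32.6% in Log, a log2 ratio of 0.43. From the counts before balancing, the interchromosomal share was 43.9% in Q (43.87 to 43.90, Clopper-Pearson) and 32.5% in Log (32.47 to 32.49). The mean contact between chromosomes was 0.72% of contact in the 10 kb squares in Q and 0.43% in Log. It was not subtracted from the shares over 60 kb, and permeabilisation differed between Log and Q. A higher ligation background in Q was therefore not separated from these rises. Neighbouring nucleosomes, at 200 to 800 bp, held 37.8% of contact up to 10 kb in Q and 41.6% in Log. Without adjacent 200 bp bins, which can hold undigested or self-ligated fragments, that log2 ratio moved from -0.14 to -0.033.

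**Figure D1:**
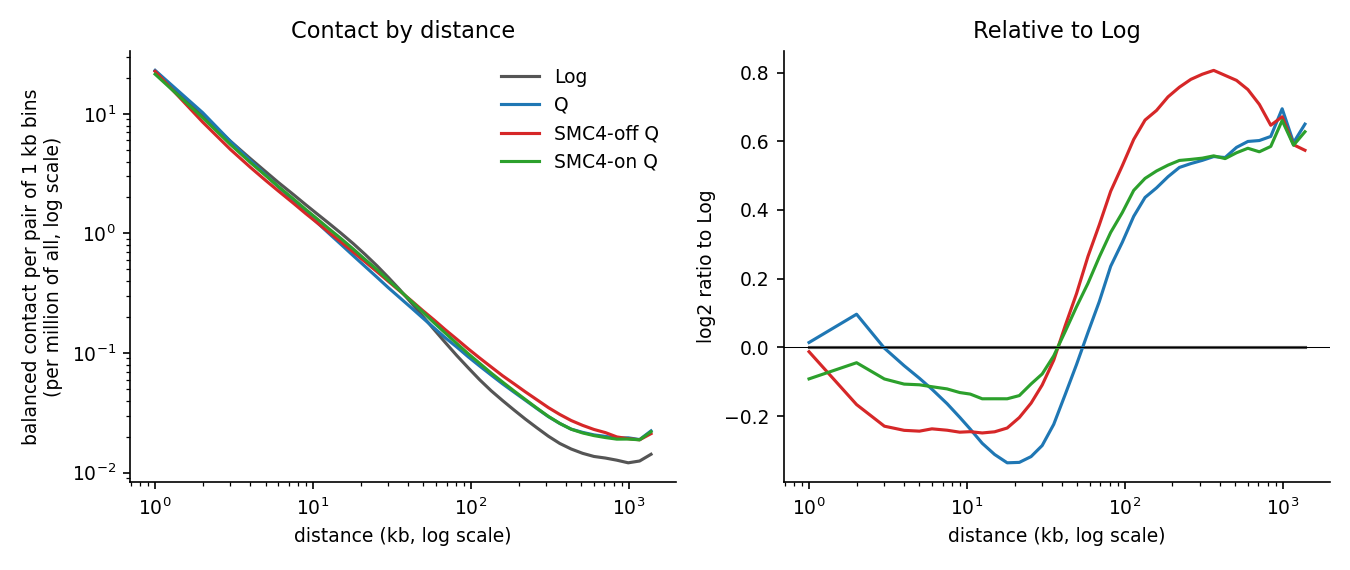
Balanced contact per pair of 1 kb bins against distance on log axes for the 4 libraries (left), and the log2 ratio of each library to Log (right), with 1 line per library and no error bars. Beyond 200 kb the 3 quiescent libraries lie above Log, with shares of 7.75% in Q, 8.90% in SMC4-off and 7.74% in SMC4-on against 5.25% in Log.

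The nuclear landmarks also differed between Q and Log. Centromeres, which yeast tethers near the spindle pole, contacted each other 13.7-fold over the interchromosomal mean in Log and 9.60-fold in Q (log2 ratio -0.51, interval -0.52 to -0.50). As a share of all contact the ratio was -0.14 (0.208% in Q and 0.230% in Log), and from counts before balancing it was more negative than the main value. Telomeres, which gather at the nuclear envelope, stood at 2.02-fold in Log and 4.39-fold in Q (1.12, interval 1.11 to 1.13). Contact between the 100 kb left and the 100 kb right of the rDNA array on chromosome XII (451786 to 469013 for the 2 copies in sacCer3/R64) was 0.180 of that at the same reference distances elsewhere in Log and 0.578 in Q, a log2 ratio of 1.68. Any further rDNA copies in these strains would lengthen the distance between the flanks. These values therefore do not measure insulation by the array apart from its length. The silent mating loci HML and HMR, at opposite ends of chromosome III, contacted each other 8.02-fold over expectation in Log and 13.96-fold in Q, from 173 and 235 contacts (log2 ratio 0.80, interval 0.52 to 1.08). With windows of 10 kb in place of 5 kb around these loci the log2 ratio was 0.43. Expected contact came from all pairs at these distances on other chromosomes, not from pairs near chromosome ends. As telomere contact also rose in Q, these values do not show a change particular to HML and HMR. Bins with tRNA genes on different chromosomes stood at 1.07-fold in Log and 1.06-fold in Q, a log2 ratio of -0.019, which turned to 0.35 when taken as a share of all contact.

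**Figure D2:**
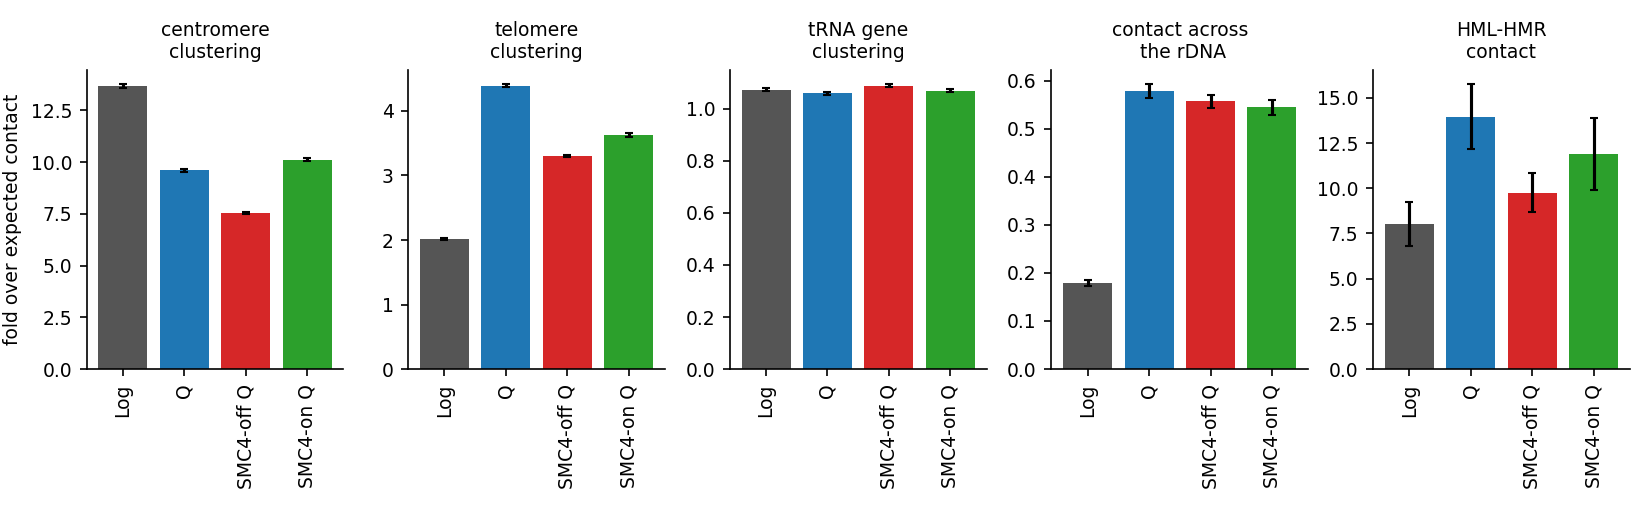
Fold over expected contact (linear axes from 0) for centromeres, telomeres, tRNA genes, the flanks of the rDNA and the HML and HMR loci, with 1 bar per library and error bars of 95% counting intervals. Centromere contact is highest in Log at 13.7-fold, and telomere contact is highest in Q at 4.39-fold.

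Domain boundaries lay at similar places in Q and Log. At the scale of several genes, 729 boundaries were called in Log and 795 in Q, with median distances between neighbours of 13 and 12 kb. Of the Log boundaries, 76.3% had a Q boundary within 2 kb, against 36.5% of boundaries shifted along the chromosomes. At the scale of single genes there were 1895 in Log and 1909 in Q, with a median distance of 5.2 kb in both. Which library looked better insulated depended on where boundaries were called: the mean insulation score, the log2 contact across a boundary over the chromosome mean, was lower in Q than in Log by a difference of -0.094 at Q boundaries and higher by 0.041 at Log boundaries. Boundaries gathered at tRNA genes, which are bound by the transcription factor TFIIIC. In Log 109 of 729 (14.95%, interval 12.4 to 17.8, Clopper-Pearson) and in Q 114 of 795 (14.3%, 11.98 to 16.97) lay within 1 kb of one, 3.53-fold and 3.39-fold over shifted boundaries. Within 2 kb these folds were 2.09 and 1.99. Shifts do not give the whole background of these folds, since on maps simulated without boundaries 7 of 73 calls in Log and 10 of 75 in Q lay near tRNA genes, where shifts gave 2.91 and 2.97. With squares free of bins without a balanced value the folds were 3.62 and 3.499. Gene starts lay within 1 kb of 93.0% of Log and 94.2% of Q boundaries, against 71.0% of shifted boundaries in both.

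Among single boundaries, those with the largest differences lay at the following genes. Repeated sequence was not scored at these sites, so none of them is marked as uncertain. The score was higher in Q than in Log at HXT1, a low-affinity glucose transporter gene (VIII 292501 to 293500, 0.25 in Q and -0.62 in Log), at TDH3, which encodes glyceraldehyde-3-phosphate dehydrogenase (VII 883501 to 884500, -0.19 and -0.97), at the cell wall gene CCW12 (XII 369501 to 370500, -0.34 and -1.09), and at the translation elongation factor gene YEF3 beside SSP120 (XII 639501 to 640500, -0.066 and -0.77). It was also higher at the hexose transporter gene HXT6 (IV 1160501 to 1161500, 0.50 and -0.31), where counts before balancing gave a difference of -0.097 in place of 0.81. Coverage before balancing in the 5 kb bin from 1160 kb there had a log2 ratio of -0.74 in Q over Log. Boundaries deeper in Q lay at IRA2, which encodes a negative regulator of Ras (XV 170501 to 171500, -1.01 in Q and -0.12 in Log), at PEX9 (XIII 309501 to 310500, -0.85 and -0.040), between PAL2 and SFB3 (VIII 298501 to 299500, -1.07 and -0.28), and at 2 sites with no gene within 500 bp (XI 20501 to 21500, -0.93 and 0.071, and VII 19501 to 20500, -0.53 and 0.23).

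Within-gene balanced contact of glycolysis genes was higher in Q, with the highest median of the gene lists fixed before the data were examined. For 3434 genes of at least 1 kb, contact within the gene was divided by that expected at the same distances, and log2 ratios are given relative to the median of all genes, which was -0.035. Of 15 measured glycolysis genes, 13 lay above the median of all genes (list median 0.57, percentile 100 among 10000 matched random lists). The highest members were ENO2, encoding enolase (1.11, 0.96 to 1.26), and ADH1, encoding the main fermentative alcohol dehydrogenase (0.98, 0.82 to 1.15). The lowest were PFK1 at -0.033 and HXK2 at -0.027, and HXK2 turned to 0.085 with bin distances of at least 3. All 14 genes of gluconeogenesis and the glyoxylate cycle lay above (0.29, percentile 99.9), led by ALD4 at 0.62 and YAT1 at 0.60 and with CAT2 at 0.045 lowest. Heat shock and stress genes lay above in 17 of 22 cases (0.18, percentile 99.96), with YGP1 at 0.48 and, at the other end, HSP42 at -0.26 and HSP104, a disaggregase, at -0.20. Of the 19 storage carbohydrate genes 15 lay above (0.090, percentile 99.6), among them the glycogen synthase gene GSY1 at 0.44 and the trehalose synthase gene TPS1 at 0.42. From counts before balancing the glycolysis median was 0.011 (percentile 98.8) and no longer the highest, the gluconeogenesis median 0.028 (percentile 96.9) and the heat shock median -0.12 (percentile 72.6). In genes of at least 2 kb heat shock stood at percentile 65.6 and gluconeogenesis, with 3 genes, at 92.6.

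Mating genes and lists of ribosome production had lower contact in Q relative to other genes under some settings and lay inside the random range under others. Of 19 mating and pheromone genes, 15 lay below the median of all genes (-0.15, percentile 0.25, but 3.33 and so inside the random range before balancing), with SST2 at -0.42 and STE4, the G protein beta subunit gene, at -0.33. Ribosome biogenesis genes lay below in 43 of 72 cases (-0.061, percentile 1.54), with ENP1 at -0.34 and NOC2 at -0.33. This list came to lie inside the random range with bin distances of at least 3 (percentile 9.48), before balancing (20.1), in genes of at least 2 kb (22.99), and without chromosome XII and regions over 400 kb from centromeres (3.08). Of 138 genes for cytosolic ribosomal proteins 17 were long enough to measure, and 10 lay below (-0.063, percentile 1.23), from RPS4A at -0.45 to RPL4B at 0.74, both uncertain with 34.7% and 72.7% of repeated sequence. That median was 0.011 (percentile 20.7) with bin distances of at least 3 and -0.55 (percentile 0) before balancing. Thus 7 of 20 measured lists lay outside the central 95% of random lists, where 1 would by chance. The lists inside it were the TCA cycle (0.14, percentile 80.1), oxidative phosphorylation (0.14, 40.3), mitochondrial ribosomal proteins (0.033, 48.5), autophagy (-0.083, 12.6), the proteasome (-0.042, 8.90), cell cycle regulators (-0.093, 5.10), DNA replication (-0.00092, 73.2), condensin and cohesin (-0.11, 19.5), meiosis and sporulation (0.029, 79.2), hexose transporters (0.082, 89.5), amino acid biosynthesis (0.11, 92.3), ergosterol biosynthesis (0.090, 72.9) and RNA polymerase III with TFIIIC (0.042, 93.6). Some left the range under other settings: before balancing meiosis and sporulation (0.41, percentile 98.6) and RNA polymerase III with TFIIIC (-0.30, 1.05), and in genes of at least 2 kb ergosterol biosynthesis (-0.22, 0.44). Of the 10 histone genes and the 24 seripauperin genes, 0 were long enough.

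The single genes with the highest ratio of Q to Log were RRN5, encoding a subunit of an RNA polymerase I activating factor (XII 423683 to 424774, observed over expected 0.620 in Q and 0.226 in Log, log2 ratio 1.49, 1.21 to 1.77), the arginase gene CAR1 (XVI 339944 to 340945, 1.29, 1.08 to 1.51) and SCS3 (VII 270997 to 272139, 1.28, 0.98 to 1.59). ENO2 and ADH1 were among them, with the proline permease gene PUT4 at 1.10, the lysine synthesis gene LYS20 at 1.09, the cell wall genes SED1 at 0.95 and HSP150 at 0.91, and the glutathione transferase gene GTO3 at 0.87. ENO2, ADH1 and LYS20 are uncertain, since 23.6%, 14.03% and 37.8% of their sequence recurs elsewhere in the genome. The lowest were VMA6 at -0.50, YMR209C at -0.49, YEL077C at -0.48 (83.8% repeated sequence), SFP1, a transcription factor of ribosomal protein genes, at -0.48, BSC5 at -0.48, TRM82 at -0.48, NAT1 at -0.46, GYP8 at -0.46, PFA3 at -0.46 and ASG1 at -0.45. Counts before balancing turned VMA6 to 0.51, TRM82 to 0.32 and GYP8 to 0.39. SMC4 itself (XII 302243 to 306499) stood at -0.21 (-0.28 to -0.15).

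**Figure D3:**
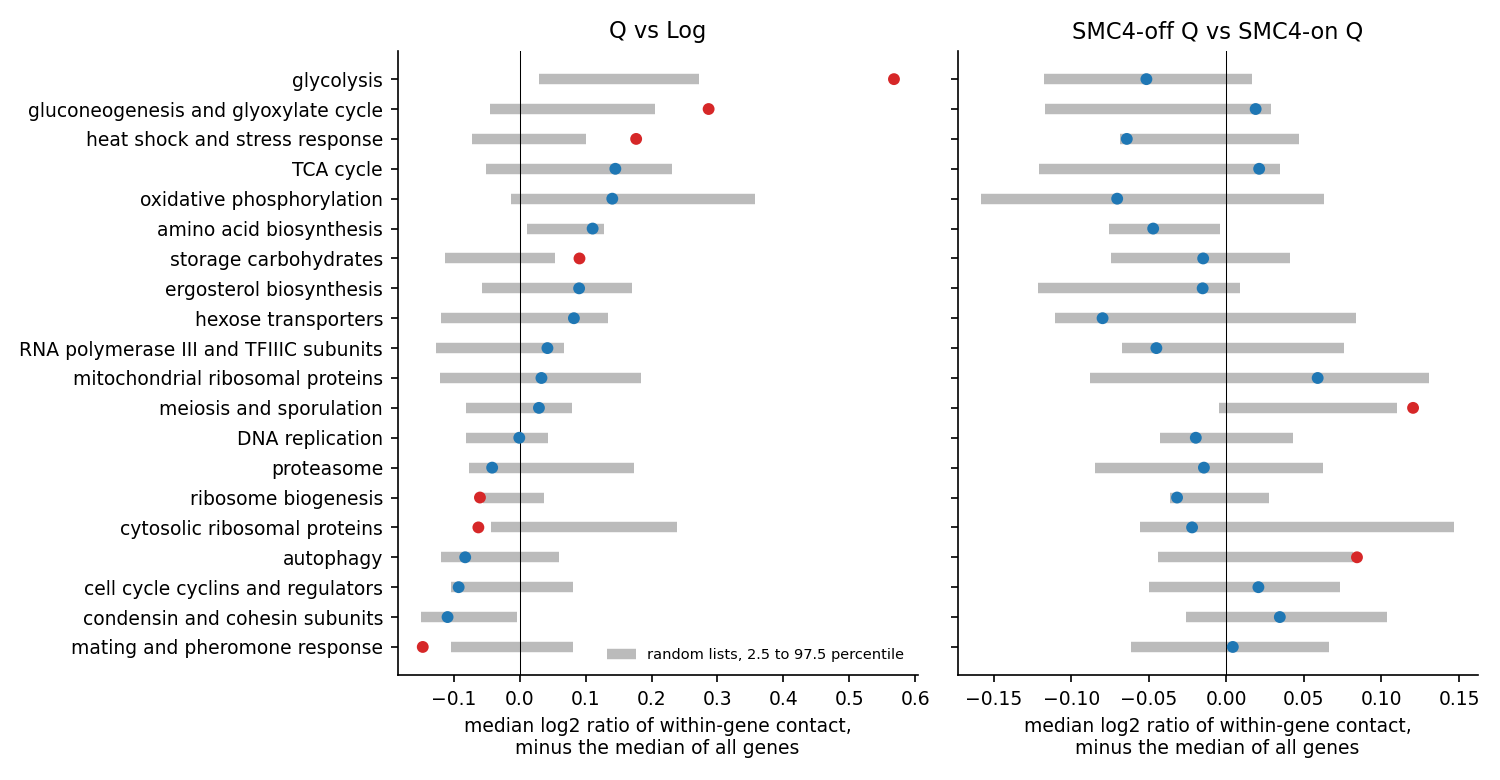
Median log2 ratio of within-gene contact of each gene list, relative to the median of all genes, for Q over Log (left) and SMC4-off over SMC4-on (right), with grey bars for the central 95% of matched random lists and red points for medians outside them. Glycolysis stands furthest right in Q over Log at 0.57, and autophagy (0.084) and meiosis (0.12) are the red points in SMC4-off over SMC4-on.

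The comparison of SMC4-off with SMC4-on asks what condensin depletion does to quiescent chromatin. Depletion itself was not measured in these libraries, and contact within SMC4 says nothing about its expression. It was 1.05 of expectation in SMC4-off and 1.36 in SMC4-on (log2 ratio -0.27, -0.34 to -0.19), but 0.27 from counts before balancing and -0.032 relative to genes within 50 kb. Doxycycline was present in SMC4-off alone, so depletion and doxycycline are not separated by this design.

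Read coverage of SMC4-off was lower far from centromeres. Before balancing, coverage right of the rDNA on chromosome XII was lower in SMC4-off than in SMC4-on in all 110 bins of 5 kb, with a median log2 ratio of -0.77 (SD over bins 0.066) relative to regions within 400 kb of centromeres. On chromosome IV beyond 1300 kb it was -0.52 in 45 bins, all lower. Over all positions more than 400 kb from a centromere, chromosome XII left out, it was -0.26, lower in 414 of 421 bins. The left part of chromosome XII stood at -0.038. SMC4-on over Q gave -0.013, -0.023, -0.016 and -0.042 in the same regions. In the outer 100 kb of the 7 arms over 500 kb, chromosome XII right left out, the median was -0.30, and in the 24 shorter arms -0.019.

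**Figure D4:**
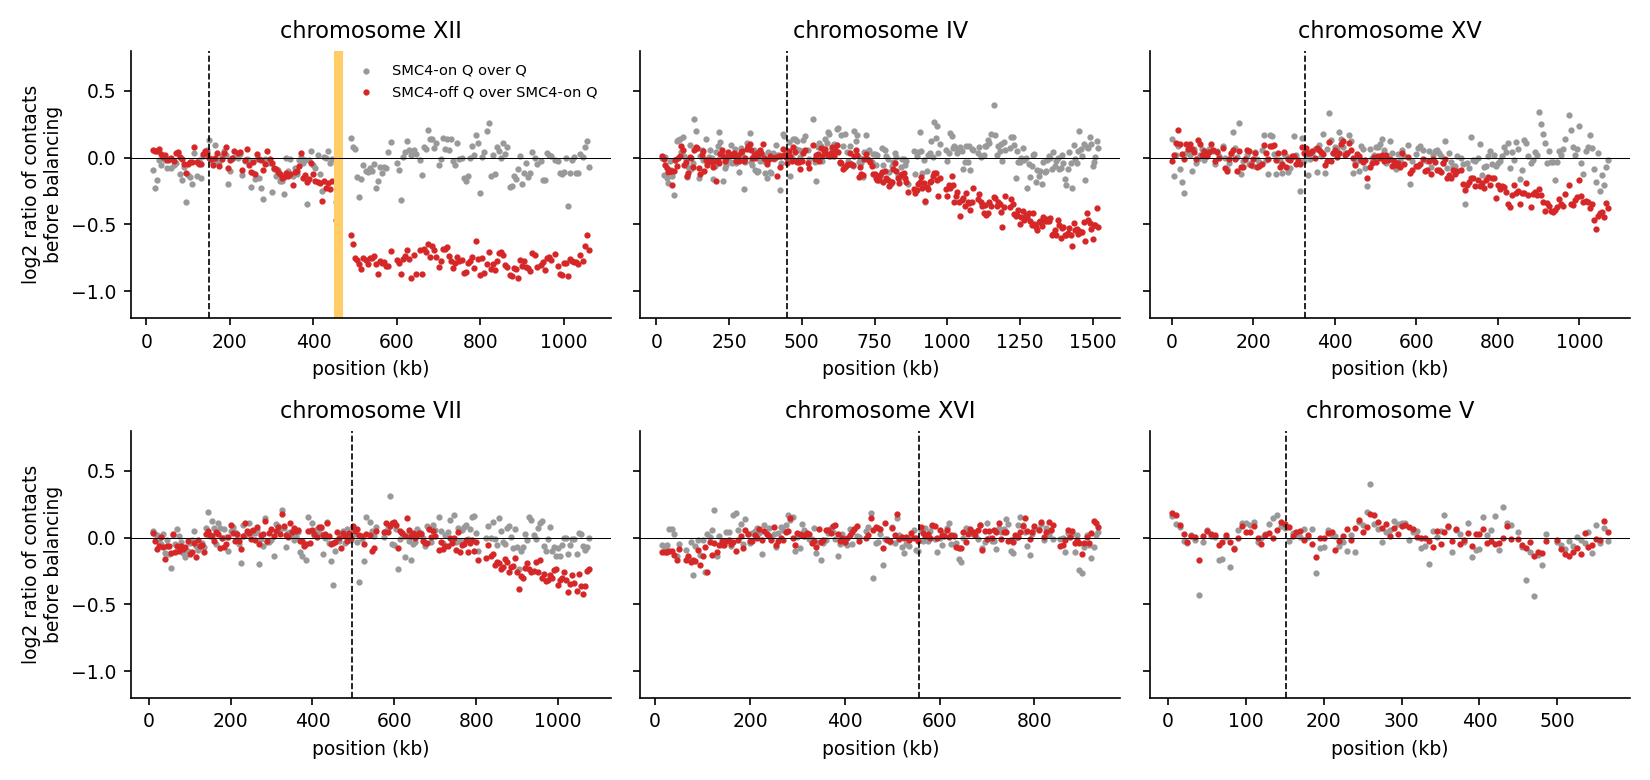
Log2 ratio of contacts per 5 kb bin before balancing, relative to regions near centromeres, along chromosomes XII, IV, XV, VII, XVI and V (position in kb), with red points for SMC4-off over SMC4-on, grey points for SMC4-on over Q, a dashed line at each centromere and a yellow band at the rDNA. Red points right of the rDNA have a median of -0.77, where grey points have a median of -0.013.

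Chromatin of SMC4-off cells had weaker domain boundaries than that of SMC4-on cells, and fewer boundaries passed the prominence threshold. Large boundaries numbered 589 in SMC4-off and 708 in SMC4-on, at median distances of 17 and 14 kb, and fine boundaries 1352 and 1831, at 6.8 and 5.2 kb. The ratio of the large counts was 0.832 and 0.820 without chromosome XII and regions over 400 kb from centromeres, where coverage was lower in SMC4-off. Fine boundaries numbered 2468 in SMC4-off and 2873 in SMC4-on with prominence 0.25, and 306 and 695 with prominence 1. The gap in counts thus depended on the threshold. Loss of boundaries was not separated from weaker boundaries falling below it. Of SMC4-off boundaries 93.2% had a SMC4-on boundary within 2 kb, while 77.5% of SMC4-on boundaries had one in SMC4-off. At the 795 large boundaries of Q, called without either SMC4 library, the score was higher, that is less insulated, in SMC4-off at 71.1%, with means of -0.26 in SMC4-off and -0.33 in SMC4-on (difference 0.070, higher on 16 of 16 chromosomes, SD 0.017). At the 1895 fine boundaries of Log it was higher at 80.9%, with means of -0.47 and -0.60 and a difference of 0.14. SMC4-on and Q, both without doxycycline, also differed. At the large boundaries of Q the difference of SMC4-on minus Q was 0.073, higher on 16 of 16 chromosomes, but these boundaries were picked in Q. At boundaries called in Log, which were picked in none of the quiescent libraries, the large difference was 0.061 for SMC4-off minus SMC4-on and 0.041 for SMC4-on minus Q, and the fine difference 0.14 and 0.036.

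**Figure D5:**
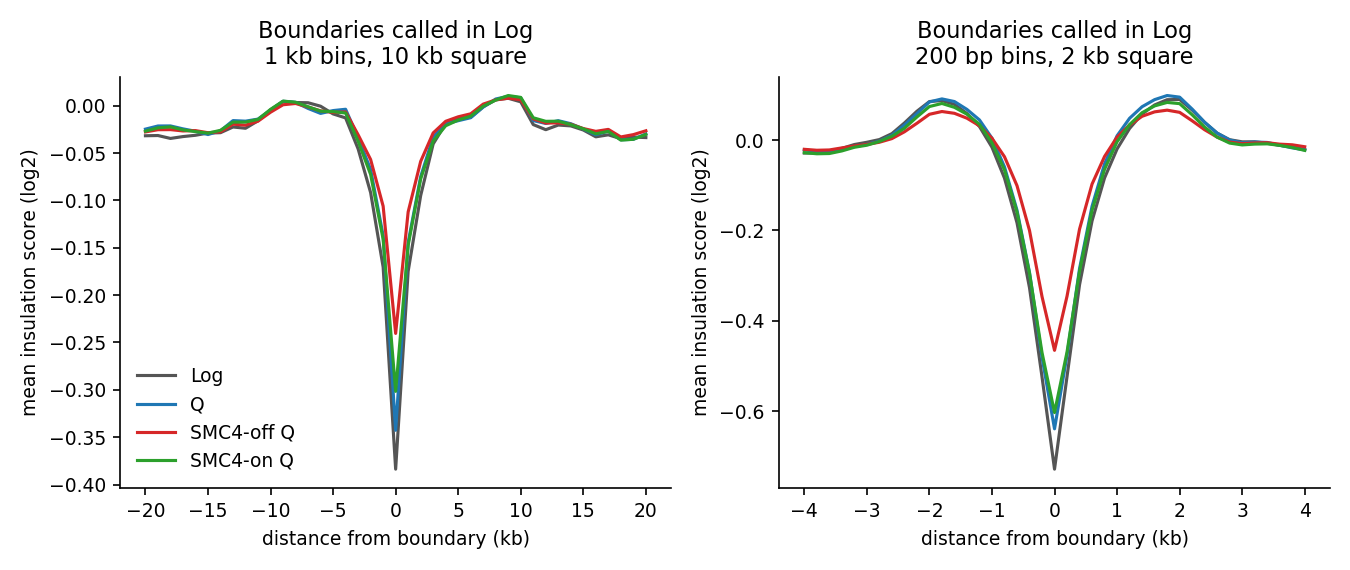
Mean insulation score (log2) against distance in kb from boundaries called in Log, at 1 kb bins (left, 729 boundaries) and 200 bp bins (right, 1895 boundaries), with 1 line per library and no error bars; Log is deepest at boundaries picked in it. At the boundary SMC4-off stands highest, at -0.24 (left) and -0.47 (right), with SMC4-on at -0.30 and -0.60.

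Insulation at tRNA genes was also weaker in SMC4-off. The mean fine score at 232 tRNA genes was -0.59 in SMC4-off and -0.80 in SMC4-on (SD over genes 0.42 and 0.42), and the large score at 225 of them -0.22 and -0.30. At 5716 gene starts the fine score was -0.16 in SMC4-off and -0.23 in SMC4-on, so the weaker score was not particular to tRNA genes. Large boundaries lay near tRNA genes at similar shares in both: 82 of 589 in SMC4-off (13.9%, 11.2 to 16.98) and 103 of 708 in SMC4-on (14.5%, 12.03 to 17.4), 3.33-fold and 3.46-fold over shifted boundaries, or 1.99 and 1.98 within 2 kb.

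In SMC4-off, the shares of contact at 3 to 10 kb and 10 to 60 kb were lower than in SMC4-on, and those at the other distances were higher. Pairs at 200 to 800 bp held 44.6% of contact up to 10 kb in SMC4-off and 38.7% in SMC4-on (log2 ratio 0.20, higher on 16 of 16 chromosomes), against 0.035 for SMC4-on over Q. At 3 to 10 kb the share was 20.7% in SMC4-off and 22.6% in SMC4-on (log2 ratio -0.13, lower on all 16), and at 10 to 60 kb 23.6% and 24.5% (-0.049, lower on 15), which became -0.029 with the interchromosomal background subtracted. At 1 to 3 kb it was 35.1% and 34.6% (0.022, higher on 16 of 16), at 60 to 200 kb 11.7% and 10.6% (0.14, higher on 16 of 16), and over 200 kb 8.90% and 7.74% (0.20). SMC4-on over Q gave -0.12 at 1 to 3 kb (lower on all 16), -0.024 at 3 to 10 kb and 0.17 at 10 to 60 kb. It gave 0.083 at 60 to 200 kb and -0.0021 over 200 kb. At 1 to 3 kb and 10 to 60 kb, SMC4-on and Q thus differed more than SMC4-off and SMC4-on did. At 10 to 60 kb the share in SMC4-off lay above the 21.7% in Q. Contact between chromosomes was 50.3% in SMC4-off and 43.8% in SMC4-on, a log2 ratio of 0.20, against -0.0020 for SMC4-on over Q. The mean contact between chromosomes was 1.02% of contact in the 10 kb squares in SMC4-off and 0.71% in SMC4-on. It was not subtracted from the shares over 60 kb. A higher ligation background in SMC4-off was therefore not separated from the rises over 60 kb and between chromosomes.

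Centromeres contacted each other less in SMC4-off, at 7.54-fold against 10.1-fold in SMC4-on (log2 ratio -0.42, -0.44 to -0.41), and by -0.26 with the centromere bin alone. As a share of all contact the fall was smaller, with 0.185% in SMC4-off and 0.218% in SMC4-on. Telomere contact was 3.30-fold and 3.63-fold (-0.13), but 0.051 as a share of all contact and -0.015 from counts before balancing. Contact across the rDNA was 0.557 and 0.544 (0.034, interval -0.020 to 0.088). That log2 ratio turned to -0.47 before balancing, where coverage right of the rDNA was lower, and to 0.26 with flanks of 50 kb. These values lie outside the counting interval with opposite signs. The direction therefore depended on the processing and was not settled. The left flank contacted other chromosomes at 1.14 of the chromosome XII mean in SMC4-off and 0.851 in SMC4-on, and the right flank at 0.750 and 0.889. HML and HMR stood at 9.77-fold from 318 contacts and 11.9-fold from 135 (-0.28, interval -0.58 to 0.0056), and tRNA genes at 1.09-fold and 1.07-fold (0.025, or 0.21 as a share of all contact).

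Few gene lists stood apart in within-gene contact between SMC4-off and SMC4-on. Of 20 measured lists 2 lay outside the random range, where 1 would by chance: autophagy (median 0.084, percentile 97.8, 13 of 21 genes above the median of all 3429 genes, which was -0.11) and meiosis and sporulation (0.12, percentile 98.8, 26 of 30 above). Without chromosome XII and regions over 400 kb from centromeres 0 lists did. Before balancing these lists stood at percentiles 71.0 and 67.8, and in genes of at least 2 kb at 92.995 and 48.6. Autophagy stood at 82.9 with the genome mean and 88.6 with bin distances of at least 3, and meiosis and sporulation at 79.2 relative to genes within 50 kb. The examples were ATG17 at 0.39, ATG39 at 0.28, ATG34 at -0.16 and ATG18 at -0.12, and SSP2, a spore wall gene, at 0.59, SPS1 at 0.29, GAS4 at -0.18 and SPR3 at -0.12. ATG39, ATG34, SPS1, GAS4 and SPR3 changed sign in counts before balancing. The lists inside the range were ribosomal proteins (-0.022, percentile 10.8), ribosome biogenesis (-0.032, 4.01), mitochondrial ribosomal proteins (0.059, 73.4), glycolysis (-0.052, 40.2), gluconeogenesis (0.019, 95.5), the TCA cycle (0.021, 95.3), oxidative phosphorylation (-0.070, 30.9), heat shock (-0.064, 3.60), storage carbohydrates (-0.015, 51.6), the proteasome (-0.014, 47.9), cell cycle regulators (0.021, 62.1), DNA replication (-0.020, 16.2), condensin and cohesin (0.034, 46.3), mating (0.0042, 55.0), hexose transporters (-0.080, 14.1), amino acid biosynthesis (-0.047, 28.5), ergosterol (-0.015, 85.7) and RNA polymerase III with TFIIIC (-0.045, 8.58). Some left the range under other settings: before balancing glycolysis (-0.35, percentile 0), heat shock (-0.15, 0.18) and amino acid biosynthesis (-0.13, 0.29), with bin distances of at least 3 glycolysis (-0.15, 1.27), and relative to genes within 50 kb RNA polymerase III with TFIIIC (-0.046, 2.20).

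The genes with the highest ratio of SMC4-off to SMC4-on were RIF2, which encodes a telomere-binding protein (XII 1041799 to 1042986, 0.70, 0.41 to 0.99), SSP2, the fatty acid elongase gene ELO3 (XII 867354 to 868391, 0.49), PBN1 at 0.47, the pantothenate kinase gene CAB1 at 0.46, NGK1 at 0.44, VPS74 at 0.44, the dihydroorotase gene URA4 at 0.43, NHX1 at 0.42 and BUR2 at 0.42. RIF2, ELO3, NGK1, URA4 and BUR2 lie right of the rDNA, and CAB1 and NHX1 beyond 1300 kb on chromosome IV. VPS74 on chromosome IV and SSP2 on chromosome XV lie over 400 kb from their centromeres. Coverage was lower in SMC4-off in these regions. Relative to genes within 50 kb, RIF2 stood at 0.41, SSP2 at 0.53, ELO3 at 0.31, PBN1 at 0.47 and CAB1 at 0.24. On that measure NGK1 stood at 0.17, VPS74 at 0.31, URA4 at 0.17, NHX1 at 0.19 and BUR2 at 0.28. ELO3 turned to -0.0044 before balancing. The lowest were SHM2, encoding serine hydroxymethyltransferase (XII 257992 to 259401, -0.54, -0.70 to -0.37), the splicing factor gene SLU7 at -0.48, ISF1 at -0.47, ETT1 at -0.46, TPO3 at -0.45, CCP1 at -0.45, FRS1 at -0.44, SSA2 at -0.43, AYT1 at -0.43 and SSB2 at -0.41. TPO3, SSA2 and SSB2 are uncertain, with 40.8%, 58.2% and 43.2% of repeated sequence, and AYT1 turned to 0.17 before balancing. SHM2, FRS1, SSA2 and AYT1 lie left of the rDNA.

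Of the boundaries that differed most, 4 of the 5 with a lower score in SMC4-off lay left of the rDNA: SSA2 (XII 95501 to 96500, -0.61 in SMC4-off and -0.25 in SMC4-on), STU2 (XII 234501 to 235500, -0.63 and -0.32), the edge of ARP6 and SMC4 (XII 301501 to 302500, -1.19 and -0.88) and CSF1 (XII 306501 to 307500, -0.96 and -0.66). Counts before balancing turned these differences to 0.14, 0.22, 0.26 and 0.24, and relative to the median within 50 kb they were -0.076, -0.022, 0.022 and 0.023. The site at SSA2 is uncertain, as 58.2% of the sequence of that gene is repeated. The other was a noncoding gene on chromosome II (326501 to 327500, -0.53 and -0.21). Higher scores were found between RPS1A and the silencing gene SIR3 (XII 1018501 to 1019500, -0.057 and -0.52), at FMP27 (XII 1051501 to 1052500, 0.23 and -0.22), the acyl-CoA synthetase gene FAA1 (XV 908501 to 909500, -0.18 and -0.56), the glucose transporter gene HXT2 (XIII 287501 to 288500, -0.24 and -0.60) and the glucan synthase gene GSC2 (VII 547501 to 548500, 0.061 and -0.30). The sites at SIR3 and FMP27 lie right of the rDNA, where coverage was lower in SMC4-off, and relative to the median within 50 kb their differences were 0.16 and 0.14 in place of 0.46 and 0.46, and that at FAA1 was 0.25 in place of 0.38.

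The comparison of SMC4-on with Q, both quiescent, asks how far these libraries differ without doxycycline. The authors named the maps of Log, Q and SMC4-off as merged and that of SMC4-on not, which bears on both comparisons with SMC4-on. Contact at 10 to 60 kb was higher in SMC4-on (24.5% against 21.7%, log2 ratio 0.17, on 16 of 16 chromosomes), a larger difference than that of SMC4-off over SMC4-on. It was 0.10 from 5 kb bins. Large boundaries numbered 708 in SMC4-on and 795 in Q. Centromere contact was higher in SMC4-on at 10.1-fold against 9.60-fold (0.076, 0.060 to 0.092), telomere contact lower at 3.63-fold against 4.39-fold (-0.27), contact across the rDNA 0.544 against 0.578 (-0.087) and HML to HMR 11.9-fold against 13.96-fold (-0.23, interval -0.54 to 0.075), which turned to 0.011 with windows of 10 kb. tRNA genes stood at 1.07-fold and 1.06-fold (0.014, or 0.12 before balancing). SMC4 had higher contact in SMC4-on (0.50, 0.42 to 0.58). Of 20 lists 3 lay outside the random range: condensin and cohesin (0.078, percentile 99.5, 9 of 14 above), led by SMC4 and SCC4 at 0.22 with PDS5 at -0.082 and SMC1 at -0.046 lowest, mating genes (0.076, percentile 99.3, 15 of 19 above) with STE4 at 0.26 and SST2 at 0.21, and amino acid biosynthesis (-0.049, percentile 0.78, 35 of 66 below), from LYS20 at -0.49, which is uncertain for its repeated sequence, and HIS2 at -0.26 to HOM6 at 0.30. SCC4, PDS5 and SMC1 changed sign before balancing. Amino acid biosynthesis came to lie inside the range with bin distances of at least 3 (percentile 5.48), before balancing (88.8), in genes of at least 2 kb (91.1), without chromosome XII and regions over 400 kb from centromeres (2.92) and relative to genes within 50 kb (15.8). Condensin and cohesin did so without those regions (92.4) and before balancing (95.4), and mating with bin distances of at least 3 (96.96). Other lists left the range: ribosome biogenesis with bin distances of at least 3 (0.042, percentile 99.6), before balancing (0.071, 99.8) and in genes of at least 2 kb (0.043, 98.1), ergosterol biosynthesis before balancing (0.043, 99.6), meiosis and sporulation with bin distances of at least 3 (-0.091, 0.31), and the TCA cycle in genes of at least 2 kb (-0.14, 2.28).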

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

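The test of the shared strain and construct and the test of origins in Q were chosen after their results were seen, and the alternatives without regions of lower coverage, with background subtracted, with thinning for insulation, and for origins were added after seeing the data. Coverage before balancing, which the comparisons of contact do not use, differed between SMC4-off and SMC4-on: the median log2 ratio was -0.77 right of the rDNA on chromosome XII, -0.52 on chromosome IV beyond 1300 kb, and -0.26 at all positions over 400 kb from a centromere without chromosome XII.

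The lower coverage of SMC4-off far from centromeres stood at -0.54 right of the rDNA when counted from pairs up to 800 bp apart, which argues against a mere lack of long-range contacts. It stood at -0.77 after correction for GC content, which argues against GC bias. SMC4-on over Q gave -0.013 there, which argues against a strain or construct present in both SMC4 libraries. These arguments rest on the region right of the rDNA. Over 400 kb from centromeres, without chromosome XII, the same measures were -0.19 (SD over bins 0.13), -0.24 and -0.016, where all contacts gave -0.26. What stays open is condensin depletion, doxycycline itself, and any difference in preparation or in pooled strains between these libraries. Doxycycline was present in SMC4-off alone, and no wild-type library with doxycycline was analysed here. SMC4-off is named as merged and SMC4-on is not, so a strain may be present in SMC4-off alone.

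The weaker insulation in SMC4-off than in SMC4-on at Q boundaries (difference 0.070) kept 99.5% of its size after subtraction of the mean contact between chromosomes, 111% without chromosome XII and regions over 400 kb from centromeres, and 99.0% with all libraries thinned to the smallest. Its size depended on the square: it was larger with squares of 5 kb and smaller with squares of 20 kb, in the same direction. The subtracted background was 1.02% of contact in the 10 kb squares in SMC4-off and 0.71% in SMC4-on, so its removal could change little. A uniform background of that size is too small to give the difference, and an uneven one was not tested. The values without regions of lower coverage and with thinning argue against balancing of those regions and against depth. Digestion or the share of short fragments stays open, as pairs at 200 to 800 bp were more frequent in SMC4-off (44.6% against 38.7%). At boundaries called in Log the difference was 0.061 (large) and 0.14 (fine), and SMC4-on differed from Q there, without doxycycline, by 0.041 and 0.036. Condensin depletion and doxycycline stay open, as the design gives no library with only one of them.

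In Log, 76 of 1895 fine boundaries lay within 200 bp of an origin of replication, 2.21-fold over shifted boundaries. Before balancing the fold was 2.84, which argues against balancing as the source. In Q the fold was 1.06, and Log was higher than Q in each setting run: 2.93 against 1.50 with prominence 0.25, 1.19 against 0.725 with prominence 1, where Log itself lay inside the range of shifts (17 of 778 boundaries, percentile 77.3), 2.84 against 1.58 before balancing, and 2.31 against 1.11 with squares free of bins without a balanced value. Whether the place of origins between genes is the source was not decided by these values. Some folds in Q lie above shifted boundaries, at percentile 99.99 with prominence 0.25 and 99.98 before balancing. That test was also chosen after its result was seen. Growth state is the biological difference the design names, and permeabilisation differed with it.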

How the results depend on the processing

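The alternatives without chromosome XII and regions over 400 kb from centromeres, with background subtracted, as shares of all contact, relative to neighbours within 50 kb, for genes from counts before balancing, and without squares holding bins with no balanced value were added after seeing the data. Among the results that answer a comparison, 84 values under an alternative stayed within their tolerance, 111 moved and 6 reversed. The tolerance was counting error for ratios and tRNA folds, the SD over chromosomes for insulation, and 1.5 times for counts. Among single genes, boundaries and other values, 296 stayed, 99 moved and 32 reversed. Counting error is small here, so many moves are slight. No paired analysis was possible because each group is 1 library, and leaving out a replicate was not possible either. The cause was not tested for any value in this part. Values are log2 ratios in the order Q over Log, SMC4-off over SMC4-on and SMC4-on over Q unless stated.

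From the 5 kb matrix, the share at 10 to 60 kb gave -0.23, -0.055 and 0.10. Without chromosome XII it gave -0.25, -0.054 and 0.17, and the share between chromosomes 0.45, 0.24 and -0.0047. With background between chromosomes subtracted the share at 10 to 60 kb gave -0.23, -0.029 and 0.18. Without bin distance 1 the share under 1 kb gave -0.033, 0.20 and 0.019. Without chromosome XII and regions over 400 kb from the centromere, the share at 10 to 60 kb gave -0.24, -0.053 and 0.18. The share under 1 kb gave -0.14 (Q over Log) and 0.033 (SMC4-on over Q), and that between chromosomes 0.46, 0.29 and 0.0085, the last reversed. Centromere contact gave -0.49 and -0.50, telomere contact -0.15 (SMC4-off over SMC4-on) and -0.25 (SMC4-on over Q), and tRNA genes 0.010 (SMC4-off over SMC4-on). There 0 gene lists lay outside the random range in SMC4-off over SMC4-on and 1 in SMC4-on over Q.

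From counts before ICE balancing, the share at 10 to 60 kb gave -0.23 and -0.047, that under 1 kb -0.18, 0.19 and 0.022, and that between chromosomes 0.43, 0.23 and -0.0038. Insulation at Q boundaries gave 0.11 (SMC4-on over Q). Centromere contact gave -0.81, -0.29 and 0.14, telomere contact 1.08, -0.015 and -0.35, tRNA genes -0.0035, 0.064 and 0.12, and contact across the rDNA 1.33, -0.47 (reversed) and -0.19. Genes that reversed in Q over Log were VMA6 (0.51), TRM82 (0.32), GYP8 (0.39), SPB4 (-0.040), JEN1 (-0.013), GLG1 (0.49), TPS3 (0.086), PRM1 (-0.025) and FUS3 (-0.37). In SMC4-off over SMC4-on they were AYT1 (0.17), ELO3 (-0.0044), SMC4 (0.27), ATG39 (-0.31), ATG34 (0.13), SPS1 (-0.074), GAS4 (0.073) and SPR3 (0.037), and in SMC4-on over Q SCC4 (-0.22), PDS5 (0.14), SMC1 (0.072) and PRM2 (0.13). The boundary at IV 1160501 reversed to -0.097 in Q over Log, and those at XII 95501, 234501, 301501 and 306501 to 0.14, 0.22, 0.26 and 0.24 in SMC4-off over SMC4-on.

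With a square of 5 kb there were 1133 large boundaries in Log, 969 in SMC4-off and 1085 in SMC4-on, and insulation differences at Q boundaries of 0.12 (SMC4-off minus SMC4-on) and 0.087 (SMC4-on minus Q). With a square of 20 kb there were 398 in Log, 493 in Q, 310 in SMC4-off and 382 in SMC4-on, and differences of 0.042 and 0.053. Prominence 0.4 gave 402, 463, 287 and 390 large boundaries and a tRNA fold of 2.55 in Log, and prominence 0.1 gave 885 in SMC4-off. Fine boundaries in Log, Q, SMC4-off and SMC4-on numbered 3392, 3129, 2355 and 3146 with a square of 1 kb, and 900, 995, 679 and 893 with a square of 4 kb. They numbered 3011, 2885, 2468 and 2873 with prominence 0.25, and 778, 760, 306 and 695 with prominence 1. At boundaries called in Log the insulation difference was 0.041 for Q minus Log (reversed) and 0.041 for SMC4-on minus Q, and at those called in SMC4-on it was 0.055 for SMC4-on minus Q. Within 2 kb of tRNA genes the folds were 2.09, 1.99, 1.99 and 1.98.

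With the centromere bin alone, centromere contact gave -0.63, -0.26 and 0.095. As a share of all balanced contact, centromeres gave -0.14 and -0.24, telomeres 1.49, 0.051 (reversed) and -0.29, and tRNA genes 0.35 (reversed), 0.21 and 0.0018. Telomere contact of the outermost 15 kb gave 1.45, -0.20 and -0.29 and of the outermost 50 kb 0.85, -0.085 and -0.23. Without bins within 60 kb of a centromere or end, tRNA genes gave -0.0023 and 0.013. Contact across the rDNA with a span of 50 kb gave 2.09 and 0.26. HML to HMR contact within 10 kb gave 0.43 (Q over Log) and 0.011 (SMC4-on over Q, reversed). With genes of at least 2 kb, 3 lists in Q over Log and 0 in SMC4-off over SMC4-on lay outside the random range, and with the genome mean in place of the chromosome mean 1 did in SMC4-off over SMC4-on. With a bin distance of at least 3, HXK2 reversed to 0.085, FUS3 to -0.026 and ATG34 to 0.15. Relative to genes within 50 kb HXK2 reversed to 0.027, and relative to the median within 50 kb the boundaries at XII 301501 and 306501 reversed to 0.022 and 0.023.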

Other observations

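At the scale of 10 kb squares, contact across centromeres was higher in the quiescent libraries than in Log. The mean large insulation score at the 16 centromeres was 0.28 in Q, 0.26 in SMC4-off and 0.28 in SMC4-on, and 0.046 in Log (SD over centromeres 0.20 in each of Log, Q and SMC4-off, and 0.19 in SMC4-on). The fine score was -0.0050 in Q, 0.11 in SMC4-off, 0.085 in SMC4-on and -0.14 in Log (SD 0.15, 0.17, 0.12 and 0.20). In Log 4 of 729 large boundaries lay within 1 kb of a centromere, where shifts gave 2.28 (percentile 87.7), and in Q 0 of 795, where shifts gave 2.48 (percentile 3.31), which allows a share of up to 0.463% (Clopper-Pearson). Both counts lie inside the central 95% of shifts, and of fine boundaries 5 of 1895 in Log and 6 of 1909 in Q lay there (0.879-fold and 1.03-fold over shifts). Of fine boundaries 2 of 1831 in SMC4-on (percentile 3.1) and 0 of 1352 in SMC4-off lay there, the latter at percentile 0.425 of shifts, which gave 4.01. Fine boundaries lay within 200 bp of a tRNA gene in 160 of 1895 cases in Log, 171 of 1909 in Q, 161 of 1352 in SMC4-off and 174 of 1831 in SMC4-on, which is 8.44-fold, 8.90-fold, 11.8-fold and 9.49-fold over shifted boundaries. On maps simulated without boundaries 4 of 72, 6 of 67, 6 of 85 and 6 of 76 fine calls lay there, where shifts gave 0.706, 0.642, 0.843 and 0.743, so shifts understate the background of these folds, and the difference between libraries was not tested. Large boundaries within 1 kb of Ty elements or LTRs, the retrotransposons of yeast and their remnants, were 2.74-fold, 2.39-fold, 2.39-fold and 2.29-fold over shifted ones.

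The fine insulation score at 304 origins of replication was -0.27 in Log, -0.11 in Q, -0.092 in SMC4-off and -0.14 in SMC4-on, while at 5716 gene starts it was -0.23 in Log, -0.23 in Q, -0.16 in SMC4-off and -0.23 in SMC4-on. Coverage before balancing of the 4 rDNA bins, over the genome median, was 2.58 in Log, 2.32 in Q, 1.41 in SMC4-off and 1.84 in SMC4-on. Reads of the repeated rDNA units fall on 2 reference copies, and how such reads were placed is not given in the sources used here.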
